A study of Sus scrofa with 6 samples.

How the data were processed

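Messenger RNA was sequenced from pig (Sus scrofa) embryos at the 8-cell stage, in 3 control libraries and 3 libraries from embryos given siRNA against a transcript that the labels call LncT. The siRNA was injected into the cytoplasm, and the libraries were made with a SMARTer kit, per the labels' protocols. Nothing in the labels says that the replicates came from separate collections or pools of embryos, so p-values measure only the spread between these samples, which may be technical.

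The submitters' processing notes name cutadapt, Bowtie2 2.3.5, StringTie 2.1.7 and the genome build Sscrofa11.1, without the role or the order of each. Bowtie2 on its own does not align across introns, and whether a spliced aligner was used with it is not given in the sources used here. The strand setting and the treatment of reads with several positions are not given in the sources used here either. Values of ribosomal protein genes, pseudogenes and other near-identical copies, and of overlapping or antisense genes, are therefore uncertain.

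The deposited table has 81774 transcript rows, with 3 values per library, per the file headers. The deposited coverage is a signal of the mean read depth over each transcript. The deposited FPKM is scaled for the length of each transcript and for the mapped fragments of the library. The deposited TPM rescales those values to the same total in every library. Read counts were not used here. Within each library, coverage divided by FPKM was a single constant, which served as a relative depth. A pair of further deposited sheets of 35395 rows each was not used. Their values in the matched columns were identical to those of the main table, and the 46379 rows they leave out were at 0 in those columns.

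Columns were matched to samples by name. The knockdown titles carry the prefix siL and the matched columns the prefix SL, while the genotype label reads LncT. A further 9 value columns, in 3 sets with the prefix ST, matched no sample title and were not used. If the prefix SL stood for an siRNA against another transcript, the comparison would be of that siRNA. LncT was not identified by the labels or the table, so the level of the target itself was not checked.

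FPKM values were summed over the transcripts of each gene, giving 29874 genes, of which 29850 were found in the RefSeq gene table of Sscrofa11.1, the source of the biotypes and coordinates. In 1758 rows the name cell held a coverage value, and these rows were named by their identifier. A further 129 rows, with 24 different date-like names, were renamed through their accession. An exact 0 may be a failed estimate, so such genes are described as listed at 0.

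Genes with a mean of at least 1 FPKM over the 6 libraries were tested, 10417 in all. The test was limma 3.58.1 in R 4.3.3 on log2(FPKM + 1), with a mean-variance trend, group as the only term, two-sided, and Benjamini-Hochberg adjustment at 0.05. Log2 changes are knockdown minus control on the log2(FPKM + 1) scale, which understates the change of weakly expressed genes. A set of 29 gene lists was tested with limma's camera at a preset correlation between genes of 0.01, and again with an estimated correlation. Of these lists, 27 had at least 3 tested members. Adjustment for the lists ran over those 27. Values of whole libraries were compared by a two-sided exact permutation test, whose smallest possible p for 3 against 3 is 0.1. Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 were used for tables and plots.

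The design, the lists, the alternatives and the rule for named genes were fixed before the data were examined, apart from 3 additions named below. Fewer than 5 genes passed the adjusted threshold, so the rule took the 10 genes with a symbol and the smallest p in each direction. It added up to 2 members with the smallest p from each list. It always took DNMT1, DNMT3A, DNMT3B, TET1, TET2, TET3, UHRF1, KDM5B, EZH2, POU5F1, NANOG, SOX2 and CDX2. Identifiers beginning with LOC, NC_, TRNA or MIR were treated as having no symbol, which passed over 3 genes in the higher direction and 7 in the lower. The rule gave 82 genes, whose values stand in the text for the most part as examples. A gene that the rule named is not reported here.

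The gene test was tested on simulated data drawn with the spread of the real genes, with 200 of the 10417 genes changed. With 6 libraries it recovered 0% of genes changed by 1 on the log2 scale, 36% of those changed by 2, 62% of those changed by 3 and 76% of those changed by 4, with 2 false calls. With the spread left after control 3 was omitted, the shares were 10%, 48%, 90% and 88%, with 3 false calls. The list test called 100% of lists of 30 genes shifted by 1 and 2% of unshifted lists. The simulated genes varied independently, which real genes do not.

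The alternatives were pseudocounts of 0.1 and 5, no filter, a mean of at least 5 FPKM, quantile normalization, median-of-ratios scaling, no trend, array weights, TPM, single transcript rows, the replicate number as a block, and each library left out in turn. Chosen after seeing the data were a scaling without mitochondrial genes, for the gene test and for the lists, and lists without members shared between lists. Tests planned for read counts were not run, since the unit was FPKM.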

Results

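The data were transcript levels of pig 8-cell embryos, the stage around which the embryo takes over transcription from stores laid down in the egg. There were 3 control libraries and 3 libraries from embryos injected with siRNA against LncT, a long non-coding RNA. Relative depth, as coverage per FPKM, was 6.69, 7.03 and 6.45 in controls 1, 2 and 3, and 6.66, 9.41 and 6.29 in knockdowns 1, 2 and 3. The numbers of genes at 1 FPKM or more were 9687 ± 575 (SD, n = 3) in controls and 10310 ± 331 (SD, n = 3) in knockdowns (exact permutation p = 0.2, adjusted p = 0.6 over 6 measures). Mitochondrial transcripts made up 30.5% ± 9.62 (SD, n = 3) of TPM in controls and 35.2% ± 8.32 (SD, n = 3) in knockdowns (exact permutation p = 0.6, adjusted p = 0.72). No 2 libraries were identical, and the median absolute log2 difference between libraries ranged from 0.29 to 0.9.

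Control 3 stood apart from controls 1 and 2. Across the 10417 tested genes, which are not independent replicates, its Spearman correlation was 0.611 with control 1 and 0.655 with control 2, against 0.922 between controls 1 and 2. Over all genes above 0 in any library these values were 0.784, 0.811 and 0.894. With knockdowns 1, 2 and 3 it was 0.900, 0.918 and 0.941, and the knockdowns correlated with each other at 0.923 to 0.943. The first principal component held 74.8% of the variance and placed controls 1 and 2 at -97.6 and -78.3, control 3 at 67.2 and the knockdowns at 29.4, 35.4 and 43.8. Detection divided the libraries in the same way, with 9237 and 9490 genes at 1 FPKM or more in controls 1 and 2, 10335 in control 3, and 9940, 10577 and 10413 in the knockdowns. Genes above 0 numbered 17966 and 18067 in controls 1 and 2, 19760 in control 3, and 19424, 20652 and 20098 in the knockdowns.

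**Figure D1:**
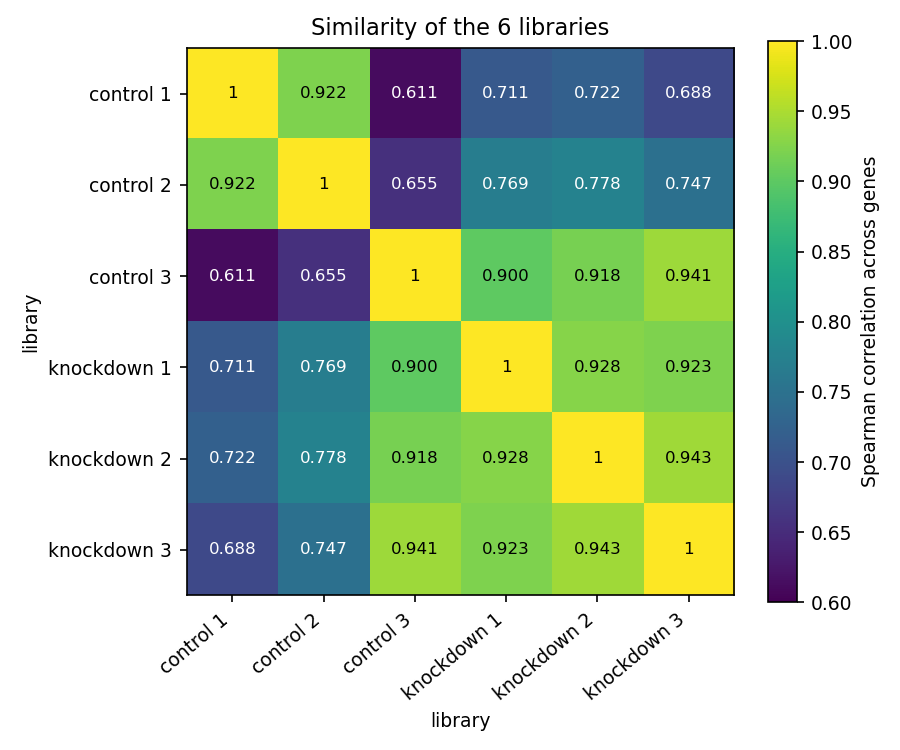
Spearman correlation across the 10417 tested genes for each pair of the 6 libraries, with both axes listing libraries and colour giving the correlation. Control 3 correlates with the knockdown libraries at 0.900 to 0.941 and with controls 1 and 2 at 0.611 and 0.655.

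The comparison of knockdown with control asks whether lowering LncT alters transcripts in the embryo, with regulators of the epigenome as the study's stated interest. DNMT3B, which adds methyl groups to unmethylated DNA, was the epigenetic regulator among the 10 genes with a symbol and the smallest p in the lower direction. It was at 9.69 ± 5.24 FPKM (SD, n = 3) in controls and 2.60 ± 1.78 (SD, n = 3) in knockdowns. TMBIM6, a membrane protein that limits cell death, had the smallest p of the named genes in the higher direction, at 14.4 ± 6.95 FPKM (SD, n = 3) against 71.4 ± 11.4 (SD, n = 3). Neither gene passed the adjusted threshold (limma adjusted p = 0.775 for each). The higher TMBIM6 value came from a single transcript that was listed at 0 in every control. With 6 libraries, 0 of 10417 genes passed in limma, and the smallest adjusted p was 0.775. At an unadjusted p under 0.05 there were 436 genes, 375 higher and 61 lower in knockdowns, where chance alone gives 521. Under quantile normalization, which moved the median change of all genes to -0.17, that split was 296 higher and 202 lower, and under median-of-ratios scaling 265 higher and 104 lower. The groups did not overlap for 456 genes that were higher and 298 that were lower, 7.2% of the genes tested, where chance gives 10%. Without control 3, 2854 genes passed, 2102 higher and 752 lower, and the groups did not overlap for 61.9% of the genes tested. Chance gives more than 10% for that smaller comparison, and leaving out any other library gave 9.7% to 13.6%. Array weights, which gave control 3 a weight of 0.113 and the other libraries 0.789 to 2.31, passed 3405 genes, 2443 higher and 962 lower.

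Among the 10 genes with a symbol and the smallest p in the higher direction, TMBIM6 (chromosome 5, 15674028 to 15692944, Sscrofa11.1) had a log2 change of 2.31 ± 0.39 (SE). Of its 75.4, 80.2 and 58.6 FPKM in the knockdowns, a single transcript made up 71.5, 74.2 and 47.0. That transcript was listed at 0 in every control, and assignment of reads between isoforms may account for such a row. PARM1 (chromosome 8, 70788134 to 70892642) was at 0.77 ± 1.07 FPKM in controls and 10.6 ± 4.61 in knockdowns (SD, n = 3). PAGE2B, a member of a germline antigen family on chromosome X (47916076 to 47919904), was listed at 0 in every control and at 4.13, 18.8 and 4.55 FPKM in the knockdowns. MAP1B, a microtubule-associated protein, was at 4.30 ± 0.24 and 11.8 ± 1.39 FPKM (SD, n = 3), with control 3 at 4.51. PDHA2, a pyruvate dehydrogenase subunit, was at 0.58 ± 0.40 and 2.99 ± 0.47 FPKM (SD, n = 3). MED9, ERICH1, GCSAML, FBXO40 and NEU3 had log2 changes of 1.52, 1.39, 1.67, 1.52 and 1.09. All 10 had a limma adjusted p of 0.775 with 6 libraries and passed without control 3. They were picked by p in these same libraries, and 2854 of all 10417 tested genes passed without control 3. Their passing is therefore no separate evidence of a knockdown effect.

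In the lower direction, BOD1, which acts in chromosome alignment, was at 106 ± 51.4 FPKM in controls and 34.2 ± 5.45 in knockdowns (SD, n = 3), a log2 change of -1.50 ± 0.43 (SE). NT5C2, a purine nucleotidase, was at 16.2 ± 5.05 and 3.17 ± 4.31 FPKM (SD, n = 3). Its span (chromosome 14, 114062451 to 114167460) overlaps that of PCGF6 (114062457 to 114287458), which leaves the values of both genes uncertain. STAT5A, a transcription factor of cytokine signalling, was at 2.84 ± 1.52 and 0.53 ± 0.25 FPKM (SD, n = 3). OSGIN2, BPGM, GRPEL2, AGTRAP, COQ7 and BORCS8 had log2 changes of -0.95, -1.10, -1.96, -0.81, -0.96 and -0.88. Knockdown and control values overlapped for GRPEL2 alone among the 10. All had a limma adjusted p of 0.775 with 6 libraries, and all but COQ7 (adjusted p = 0.0531) passed without control 3. These genes too were picked by p in the same libraries, so passing is no separate evidence.

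Among the enzymes of DNA methylation, DNMT1, which copies methylation onto new DNA strands, was the most abundant of the list, at 1838 ± 704 FPKM in controls and 1297 ± 467 in knockdowns (SD, n = 3). Its log2 change was -0.48 (95% interval -1.47 to 0.52), and control 3 lay at 1025 FPKM, below controls 1 and 2 at 2232 and 2258. Without control 3 the log2 change of DNMT1 was -0.855 (limma adjusted p = 0.0756). DNMT3B (chromosome 17, 36345715 to 36386076) had a log2 change of -1.57 (95% interval -2.83 to -0.31), and control 3, at 4.75 FPKM, lay closest to the knockdowns, whose highest value was 4.46. UHRF1, the partner that guides DNMT1, was at 12.2, 8.40 and 1.88 FPKM in the controls and 2.51, 4.66 and 1.83 in the knockdowns. DNMT3A was at 5.55 ± 2.16 and 4.10 ± 0.67 FPKM (SD, n = 3). Of the TET enzymes, which oxidise methylated cytosine, TET1 had a log2 change of 0.34 and TET3 of -0.28, or 0.28 and -0.58 without control 3. TET2 had a log2 change of 0.05, which turned negative under quantile normalization, with TPM and without control 3. GADD45A, tied to demethylation and to DNA damage, was at 1.11 ± 0.18 and 4.26 ± 2.20 FPKM (SD, n = 3). The list of 18 tested genes had 9 members above 0 and 9 below, with a median log2 change of -0.07, a mean of 0.16 and a camera direction of down (camera adjusted p = 0.90). The median ranged from -0.14 to 0.10 with 1 library left out. Without control 3, where 2854 of all 10417 tested genes passed, 4 members passed in the higher direction and 2 in the lower. GADD45A was among the former, with a log2 change of 1.31 (limma adjusted p = 0.0362), and the latter were DNMT3B and UHRF1, with -1.96 and -1.54 (limma adjusted p = 0.0194 and 0.0192).

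**Figure D2:**
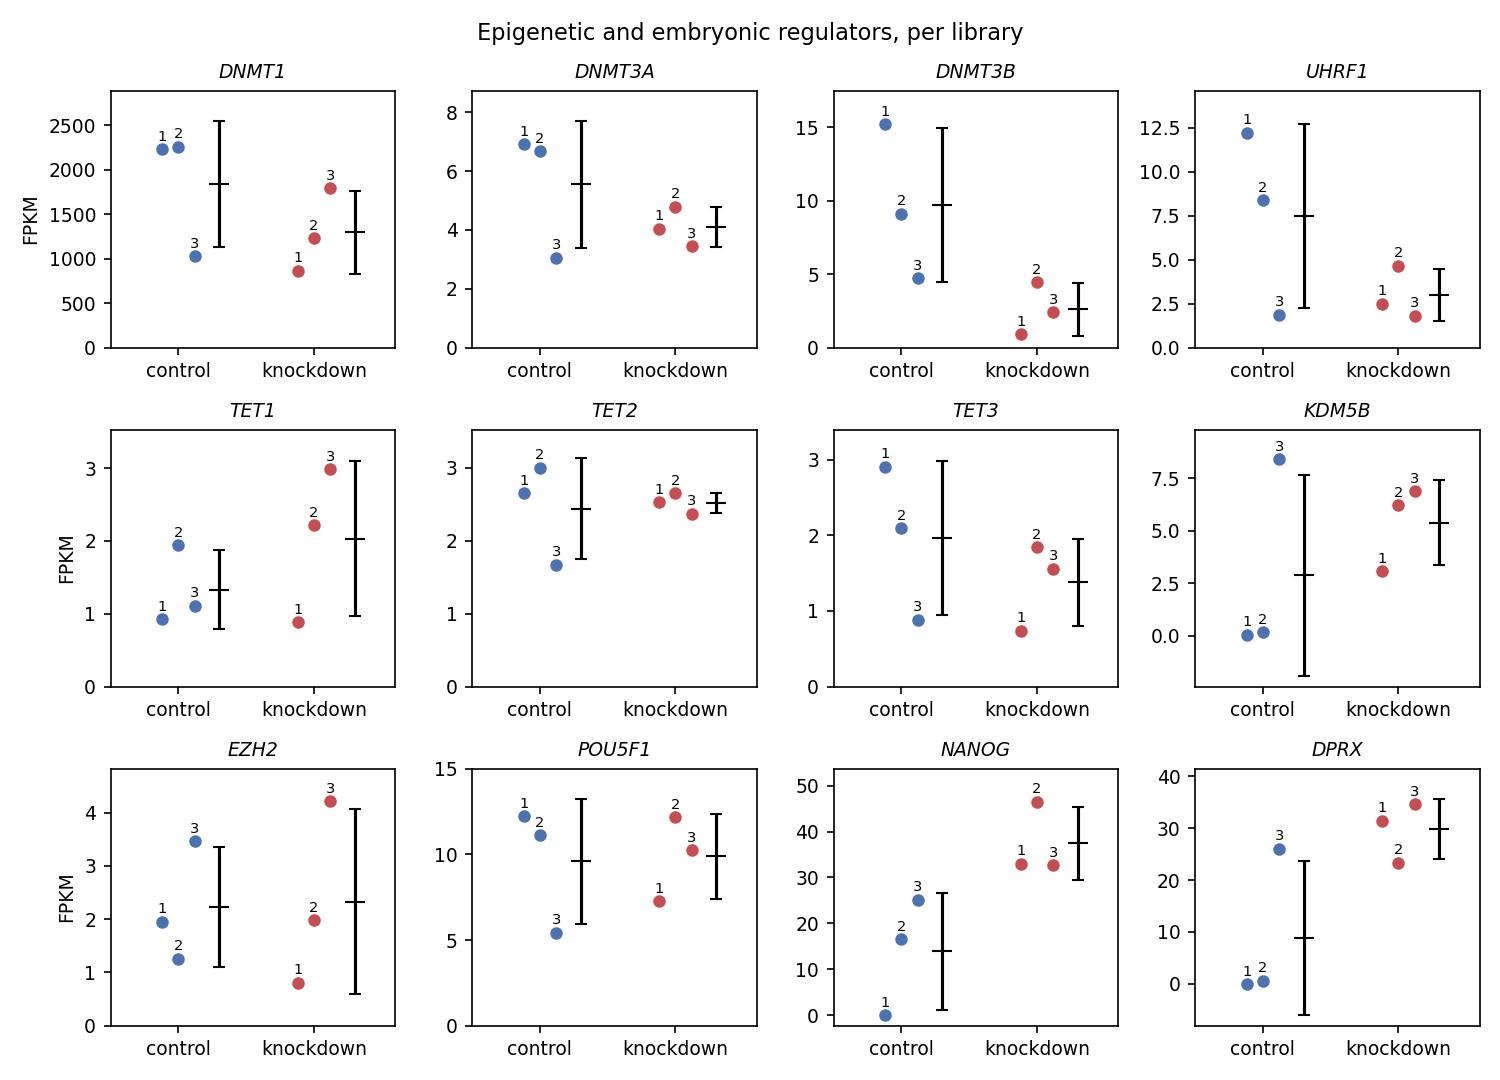
FPKM of 12 genes in each library, with blue points for controls, red points for knockdowns, numbers for the replicate, and black bars for the mean and SD of 3 libraries. Control 3 lies nearer to the mean of the knockdowns than to the mean of controls 1 and 2 for every gene shown except TET1.

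With 6 libraries the 6 lists of histone modifiers and chromatin remodellers held 0 genes past the adjusted threshold, and none was called by camera. Without control 3, members passed in each list, among them HDAC3 (log2 change -1.38, limma adjusted p = 0.00868), KDM5B (2.46, 0.00239) and SETD2 (2.74, 0.000823). For each of these genes, control 3 itself lay within or beyond the values of the knockdowns. Without control 3, 2854 of all 10417 tested genes passed, so members that passed are not particular to these 6 lists. Histone acetyltransferases and deacetylases (19 tested) had a median of 0.13 and a mean of 0.07, with a camera direction of down (adjusted p = 0.90), and the median was -0.11 under quantile normalization and -0.03 to 0.15 with 1 library left out. Without control 3, 6 members passed higher and 2 lower. HDAC3 was at 2.67 ± 1.61 FPKM in controls and 0.76 ± 0.27 in knockdowns, and SIRT7 at 1.03 ± 1.06 and 2.13 ± 0.29 (SD, n = 3). For HDAC3, control 3 lay at 0.85 FPKM, within the knockdown range of 0.53 to 1.07. For H3K4 methylation (15 tested) the median was -0.29 (adjusted p = 0.26), or -0.50 to -0.12 with 1 library left out. It was -0.50 without control 3, where 3 members passed higher and 2 lower. KDM5B, a demethylase of that mark, was at 0.06 and 0.18 FPKM in controls 1 and 2, at 8.42 in control 3 and at 3.09, 6.22 and 6.88 in the knockdowns, while KDM5C was at 0.96 ± 1.0 and 2.67 ± 0.81 FPKM (SD, n = 3). For H3K9 methylation and heterochromatin (15 tested) the median was -0.09 (adjusted p = 0.36), -0.29 under quantile normalization and 0.03 without control 3, where 0 members passed higher and 3 lower. This list had EHMT2 at 3.54 ± 2.09 and 1.42 ± 0.64 FPKM and JMJD1C at 3.46 ± 0.50 and 5.22 ± 1.16 (SD, n = 3). Control 3 lay within the knockdown range for EHMT2, SIRT7 and KDM5C, at 1.31, 2.25 and 2.07 FPKM, and below every knockdown for JMJD1C.

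For Polycomb and H3K27 methylation (20 tested) the median was 0.00 and the mean 0.39 (adjusted p = 0.61). Without control 3 the median was 0.26, and 6 members passed higher and 1 lower, with all 6 libraries giving BMI1 at 1.20 ± 0.71 and 3.07 ± 1.14 FPKM and PCGF6 at 9.72 ± 3.81 and 17.9 ± 3.48 (SD, n = 3). The H3K27 methyltransferase EZH2 was at 2.22 ± 1.13 and 2.33 ± 1.73 FPKM (SD, n = 3), a log2 change of -0.03. Other histone marks (9 tested) had a median of -0.18 and a mean of 0.07, with a camera direction of down (adjusted p = 0.78). Without control 3 the median was -0.49, and 2 members passed higher and 1 lower. With 1 library left out the median ranged from -0.49 to 0. In that list NSD1 was at 9.67 ± 4.42 and 18.0 ± 1.41 FPKM, and SETD2 at 5.90 ± 8.97 and 10.4 ± 1.56 (SD, n = 3). SETD2 was at 0.39 and 1.06 FPKM in controls 1 and 2 and at 16.2 in control 3, above every knockdown. Chromatin remodellers and histone chaperones (27 tested) had a median of -0.15 (adjusted p = 0.32), or -0.33 without control 3, where 3 members passed higher and 1 lower. The median turned to 0.04 without knockdown 1. In this list stood BRDT at 127 ± 87.6 and 209 ± 47.0 FPKM and BRD9 at 1.0 ± 0.11 and 1.94 ± 0.06 (SD, n = 3). Control 3 lay within the knockdown range for BMI1, PCGF6 and BRDT, and below every knockdown for NSD1 and BRD9.

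Genes of zygotic genome activation stood higher in knockdowns than in controls 1 and 2, and control 3 stood with the knockdowns. In this list 25 of 26 tested members had a log2 change above 0, with a median of 0.95 (camera adjusted p = 2.1e-05). The call was lost with an estimated correlation (adjusted p = 0.70). Mean log2(FPKM + 1) was 1.81, 2.69 and 4.27 in the controls and 4.09, 4.24 and 4.23 in the knockdowns. DPRX, a homeobox gene of early embryos, was listed at 0 in control 1 and stood at 0.62 in control 2, at 26.1 in control 3 and at 31.4, 23.3 and 34.7 FPKM in the knockdowns. NFYB, a subunit of a CCAAT-binding factor, was at 24.5 ± 4.92 and 43.3 ± 4.14 FPKM (SD, n = 3), with no overlap between groups. With 6 libraries 0 members passed, and without control 3 there were 14, all of them higher. The median was 1.52 without control 3 and 0.60 without control 1.

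Maternal and oocyte transcripts ran the other way, with 32 of 36 members below 0 and a median of -0.35 (camera adjusted p = 0.0012, and adjusted p = 0.70 with an estimated correlation). Mean log2(FPKM + 1) was 5.55, 5.40 and 4.37 in the controls and 4.51, 5.09 and 4.72 in the knockdowns. DAZL, a germ cell RNA-binding protein, was at 71.6 ± 9.93 and 46.9 ± 1.48 FPKM, and the oocyte transcription factor NOBOX at 2.20 ± 1.11 and 0.93 ± 0.86 (SD, n = 3). Without control 1 the call ended (camera adjusted p = 0.093). The median was -0.75 without control 3, -0.12 without control 1 and -0.14 without control 2. Without control 3, 14 members passed lower and 1 higher. The machinery that clears maternal mRNA (23 tested) had a median of -0.02, or -0.12 to 0.08 with 1 library left out, a mean of 0.08 and a camera direction of down (adjusted p = 0.91), with YTHDF3 at 11.4 ± 6.10 and 20.3 ± 4.88 FPKM and ZCCHC6 at 16.4 ± 4.87 and 25.5 ± 3.57 (SD, n = 3).

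Cytosolic ribosomal protein genes had the smallest camera p of the 27 lists, with 65 of 67 members above 0 and a median of 1.25 (camera adjusted p = 2.9e-10, and adjusted p = 0.70 with an estimated correlation). Their mean log2(FPKM + 1) was 1.26, 1.51 and 4.42 in the controls and 3.39, 4.04 and 3.63 in the knockdowns, so that control 3 lay above every knockdown. RPS15A was at 0.71 ± 0.54 and 3.09 ± 0.48 FPKM, and RPS25 at 5.58 ± 7.71 and 13.5 ± 3.92 (SD, n = 3). Without control 3, 51 members passed, all higher. The median was 2.05 without control 3, 0.68 without control 1 and 0.75 without control 2. Reads of these genes can be shared with many pseudogenes. Ribosome biogenesis (32 tested) had a median of 0.87 (camera adjusted p = 0.00024, and adjusted p = 0.70 with an estimated correlation). Its mean log2(FPKM + 1) was 2.41, 2.73 and 4.56 in the controls and 3.94, 4.29 and 4.44 in the knockdowns. Control 3 thus lay above every knockdown in this list too. The list median was 1.5 without control 3, where 20 members passed higher, and 0.39 without control 1. UTP3 was at 9.86 ± 8.93 and 40.7 ± 7.24 FPKM, and the nucleolar protein FBL at 3.34 ± 5.19 and 11.6 ± 4.17 (SD, n = 3).

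Nuclear genes of oxidative phosphorylation (24 tested) had a median of 1.11 (camera adjusted p = 0.0037, and adjusted p = 0.70 with an estimated correlation). Their mean log2(FPKM + 1) was 2.19, 2.17 and 4.80 in the controls and 3.83, 4.39 and 4.20 in the knockdowns, and the call ended without control 2 (adjusted p = 0.30). The median was 1.82, 0.57 and 0.65 without control 3, control 1 and control 2, and 17 members passed higher in the first case. NRF1, a transcription factor of nuclear genes for mitochondrial proteins, was at 1.38 ± 1.23 and 3.65 ± 1.15 FPKM (SD, n = 3). Splicing and mRNA processing (37 tested) had a median of 0.44 (camera adjusted p = 0.016, and adjusted p = 0.70 with an estimated correlation). Its mean log2(FPKM + 1) was 3.47, 3.79 and 4.88 in the controls and 4.35, 4.77 and 4.64 in the knockdowns. Control 3 lay above every knockdown here as well. The call of this list ended without control 1 (adjusted p = 0.17), without control 2 (0.22) or without knockdown 2 (0.056). Its median was 0.73, 0.20 and 0.25 without control 3, control 1 and control 2, and 0.24 under quantile normalization, and 15 members passed higher without control 3. SRSF11 was at 32.3 ± 38.2 and 70.6 ± 10.8 FPKM, and SRSF7 at 35.7 ± 35.9 and 85.1 ± 7.0 (SD, n = 3). Control 3 lay within the knockdown range for SRSF11, at 76.2 FPKM, and below every knockdown for SRSF7, at 74.5 FPKM.

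Glycolysis and pyruvate metabolism (19 tested) had a median of 0.71 (camera adjusted p = 0.018, and adjusted p = 0.70 with an estimated correlation). Its mean log2(FPKM + 1) was 2.32, 2.35 and 3.30 in the controls and 3.11, 3.44 and 3.59 in the knockdowns. The call ended without control 2 (adjusted p = 0.066) or without knockdown 3 (0.076), with medians of 0.44 and 0.23, and once members shared with other lists were removed (0.061). Without control 3, 7 members passed higher. Under quantile normalization the median was 0.35, with no filter 0.26 and with a mean of at least 5 FPKM 1.08. TPI1, a glycolytic enzyme, was at 3.87 ± 0.26 and 9.88 ± 4.49 FPKM, and the glucose transporter SLC2A3 at 1.87 ± 2.40 and 6.65 ± 3.26 (SD, n = 3). The 13 mitochondrially encoded genes had a median of 0.22 (adjusted p = 0.26), or 0.01 to 0.63 with 1 library left out, the highest without control 3. Without knockdown 2 they were called (adjusted p = 0.022, and adjusted p = 0.72 with an estimated correlation). With 6 libraries COX2 was at 8350 ± 3997 and 12020 ± 3473 FPKM and ATP8 at 32120 ± 18290 and 42160 ± 15110 (SD, n = 3).

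**Figure D3:**
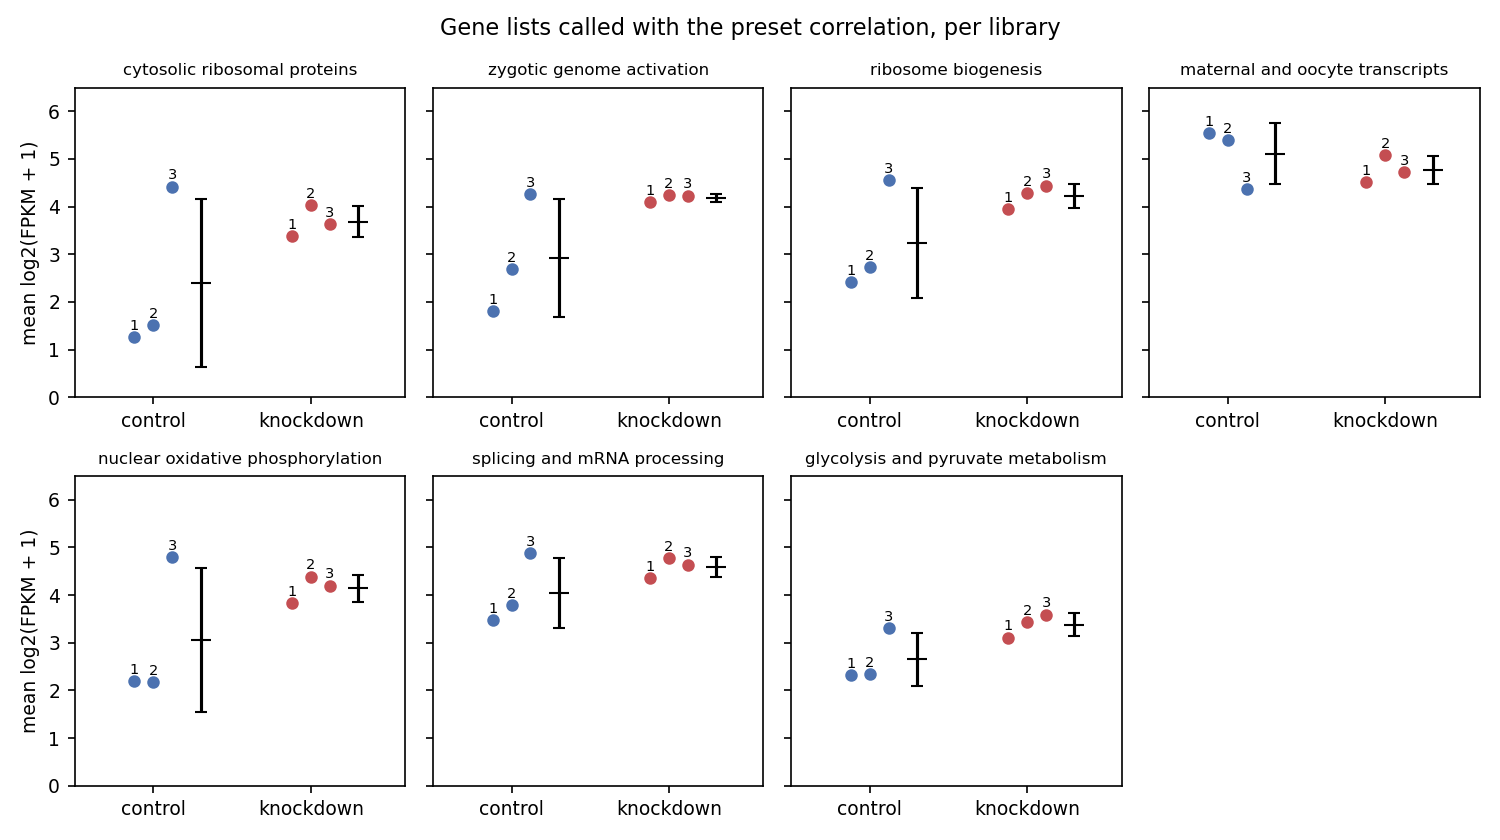
Mean log2(FPKM + 1) of the 7 gene lists called by camera with the preset correlation, in each library, with blue points for controls, red points for knockdowns, numbers for the replicate, and black bars for the mean and SD of 3 libraries. Control 3 lies at 4.27 in zygotic genome activation, against 1.81 and 2.69 in controls 1 and 2 and 4.09 to 4.24 in the knockdowns.

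Pluripotency and inner cell mass genes (20 tested) had a median of 0.34 (adjusted p = 0.21). NANOG, a pluripotency factor, was at 0.04, 16.5 and 25.2 FPKM in the controls and 33.0, 46.5 and 32.7 in the knockdowns, with no overlap and a limma adjusted p of 0.775. POU5F1 was at 9.61 ± 3.66 and 9.89 ± 2.48 FPKM (SD, n = 3), with a log2 change of 0.08 that turned negative under quantile normalization and with TPM. ID1 was at 1.45 ± 1.34 and 4.09 ± 2.47 FPKM (SD, n = 3). SOX2 stayed under the filter, with a highest value of 0.23 FPKM, as did CDX2, with 0.018. Trophectoderm genes (13 tested) had a median of -0.37 (adjusted p = 0.081), or -0.60 to -0.16 with 1 library left out, the lowest without control 3. Without knockdown 3 they were called (adjusted p = 0.039, and adjusted p = 0.75 with an estimated correlation). With 6 libraries TEAD1 was at 8.72 ± 1.6 and 5.94 ± 1.30 FPKM and TFAP2C at 5.45 ± 6.5 and 9.52 ± 1.95 (SD, n = 3). For TFAP2C, control 3 lay at 12.8 FPKM, above every knockdown, against 0.45 and 3.11 in controls 1 and 2. For TEAD1 every control lay above every knockdown.

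With 6 libraries none of the remaining lists was called. Cell cycle genes (34 tested) had a median of -0.23 (adjusted p = 0.21), or -0.43 (without control 3) to -0.10 with 1 library left out. In this list CCND2 was at 1.72 ± 2.86 and 7.90 ± 2.52 FPKM and ORC1 at 6.83 ± 5.26 and 18.7 ± 4.50 (SD, n = 3). Genes of p53, DNA damage and apoptosis (24 tested) had a median of 0.30 (adjusted p = 0.17), or 0.15 to 0.44 with 1 library left out. In this list BID was listed at 0 in controls 1 and 2 and at 35.0 FPKM in control 3, against 24.8, 53.8 and 37.5 in the knockdowns. Interferon and double-stranded RNA response genes (10 tested) had a median of -0.12, or -0.14 to 0.03 with 1 library left out, a mean of 0.19 and a camera direction of down (adjusted p = 0.93). In this list OAS1, a sensor of double-stranded RNA, was at 0.63 ± 0.52 and 3.0 ± 1.48 FPKM, and MX1 at 22.2 ± 14.1 and 8.04 ± 1.58 (SD, n = 3). Oxidative and endoplasmic reticulum stress genes (26 tested) had a median of 0.19, or -0.01 under quantile normalization (adjusted p = 0.32), with the chaperone HSPA5 at 25.3 ± 18.8 and 64.3 ± 17.6 FPKM and TRIB3 at 1.33 ± 2.06 and 4.78 ± 1.0 (SD, n = 3). Imprinted genes (10 tested) had a median of -0.04, or -0.06 to 0.06 with 1 library left out, a mean of 0.15 and a camera direction of up (adjusted p = 0.93), with GNAS at 1.21 ± 0.47 and 2.60 ± 0.43 FPKM and UBE3A at 5.54 ± 7.36 and 12.3 ± 1.28 (SD, n = 3). Genes of m6A RNA methylation (16 tested) had a median of 0.06, or -0.16 under quantile normalization (adjusted p = 0.78), with YTHDF2 at 16.0 ± 9.41 and 26.1 ± 3.96 FPKM (SD, n = 3). Reference genes (14 tested) had a median of 0.34 (adjusted p = 0.31), or 0.14 to 0.53 with 1 library left out. Among them PGK1 was at 9.13 ± 1.77 and 17.7 ± 7.18 FPKM and H2AFZ at 586 ± 719 and 937 ± 161 (SD, n = 3). Across the genes named in these lists, control 3 lay within the knockdown range for BID, MX1, HSPA5, TRIB3 and YTHDF2. It lay above every knockdown for UBE3A, at 14.0 FPKM, and for H2AFZ, at 1412 FPKM. For CCND2, ORC1, OAS1, GNAS and PGK1 it lay below every knockdown.

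Markers of other cell types were few. Cumulus and granulosa cell markers (6 tested) had a median of 0.28, or -0.03 under quantile normalization (adjusted p = 0.43). AREG, a growth factor of cumulus cells, was listed at 0 in controls 1 and 2 and stood at 1.56 FPKM in control 3 and at 2.47, 4.93 and 7.39 in the knockdowns, and SERPINE2 was at 4.28 ± 1.45 and 5.54 ± 0.90 (SD, n = 3). AREG was the 1 gene of its list that passed when adjusted over the list alone, and in every other list that count was 0 with 6 libraries. Fibroblast and stromal markers (3 tested) had a median of -0.17, or 0.05 with TPM and -0.44 to 0.02 with 1 library left out (adjusted p = 0.27), with TAGLN at 4.99 ± 1.49 and 2.36 ± 0.97 FPKM and FBN1 at 7.58 ± 2.93 and 6.45 ± 1.62 (SD, n = 3). Blood and immune markers (2 tested, so not put to camera) had a median of -0.34, with CD3E at 1.74 ± 0.92 and 0.89 ± 0.09 FPKM and PECAM1 at 1.47 ± 0.57 and 1.11 ± 0.06 (SD, n = 3). The 1 tested sperm marker, ODF2, was at 2.03 ± 0.82 and 1.89 ± 0.54 FPKM (SD, n = 3).

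The level of LncT itself was not checked, and the matched columns carry the prefix of the sample titles rather than the name LncT. Of the 6 libraries, control 3 was the one whose omission moved the count of genes past the threshold, with 0 genes passing when any other library was left out, while list calls also ended without other libraries.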

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

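The scaling without mitochondrial genes and the lists without shared members were chosen after seeing the data. The count of 0 genes past the threshold held under 10 of the 12 settings that kept all 6 libraries, with 200 to 1004 genes at an unadjusted p under 0.05, or 747 with the replicate block. It became 3405 (2443 higher, 962 lower) with array weights and 14 (9 higher, 5 lower) with single transcript rows. Leaving out 1 library gave from 0 to 2854 genes, from 0 to 2102 higher and from 0 to 752 lower, the highest each time without control 3, and from 102 to 4506 at an unadjusted p under 0.05. Array weights changed the weight of every library, giving control 3 0.113 and the others 0.789 to 2.31. That fit drew little on control 3 and is not independent of the one without it. The cause of the change in count was not tested for array weights or for transcript rows.

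Camera called 7 lists, 6 to 7 under the other settings with all libraries and the preset correlation, 6 without shared members (glycolysis then at adjusted p = 0.061), 0 with an estimated correlation, and from 4 (without control 2) to 7 with 1 library left out. The 7 were not always the same lists, as mitochondrially encoded genes were called without knockdown 2 (adjusted p = 0.022) and trophectoderm genes without knockdown 3 (0.039). The medians of all 7 kept their direction in every alternative. Of the 22 lists not called, the median turned in at least one alternative for 14. The called medians moved by over 1.5 times for 6 lists with a pseudocount of 5 (0.25 to 0.56), 6 with array weights (-0.69 to 2.08), 2 with a pseudocount of 0.1 (1.42 and 2.13), and 6, 5 and 6 without controls 1, 2 and 3.

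With the replicate block, 0 genes and 7 lists passed. Deviations of libraries with the same number correlated at 0.08, 0.06 and 0.23, the last being the highest of all pairs. Controls 1 and 2 each correlated better with another number. Deviations within a group sum to 0, and control 3 stood far from controls 1 and 2. The check therefore could not decide on pairing for numbers 1 and 2. The numbers were not taken to pair the samples, since the labels state no pairing.

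Of 82 named genes, 77 kept their direction wherever an alternative gave a value (all 17 alternatives for 38 genes, and 16 for 44 that a stricter filter or the scaling left out), 61 passed with array weights and 59 without control 3. Of all 10417 tested genes, 3405 and 2854 passed in those settings. Most named genes were picked by p in these same libraries, so these counts are no separate evidence. The log2 change turned for 5 named genes near 0, and the cause was not tested. Array weights gave 0.25 for ODF2, -0.13 for TET2, 0.47 for EZH2 and -0.11 for POU5F1. Quantile normalization gave -0.12 for TET2 and -0.037 for POU5F1, TPM -0.045 and -0.032, and a pseudocount of 5 gave 0.006 for EZH2. With 1 library left out, ODF2 ranged from -0.25 to 0.15, FBN1 from -0.44 to 0.072, TET2 from -0.12 to 0.17, EZH2 from -0.42 to 0.35 and POU5F1 from -0.25 to 0.28. Depth is known only as a relative value, so no limit from counts was set.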

Other observations

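All tests of explanations below were chosen after the results they concern had been seen.

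Long non-coding RNAs made up 1213 of the tested genes, and 0 passed the adjusted threshold in limma, with 35 higher and 10 lower at an unadjusted p under 0.05. Without control 3, 120 were higher and 59 lower past the threshold. The 8344 protein-coding genes gave 1691 higher and 662 lower without control 3, and the 747 pseudogenes 253 higher and 27 lower. ATP6 and ATP8, on the mitochondrial genome, were the most abundant transcripts by mean FPKM. LOC100621706, a protein-coding gene on chromosome 5 (19669343 to 19676417), took 7.58%, 4.96% and 1.65% of TPM in the controls and 3.41%, 3.01% and 1.95% in the knockdowns (exact permutation p = 0.4, adjusted p = 0.72 over 6 measures), and was picked after its values were seen.

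Control 3 lay with the knockdown libraries. The tables argue against depth, as control 3 had 6.45 coverage per FPKM and control 2 had 7.03, and scaling by mitochondrial transcripts would leave ranks alone, yet the mean Spearman correlation with controls 1 and 2 was 0.633 against 0.922 between those controls (over all genes 0.784 and 0.811 against 0.894, a gap just under the 0.1 set for this test). An exchange with a knockdown library would need one lying with controls 1 and 2, and on an axis from those controls at 0 to the knockdowns at 1 the lowest knockdown lay at 0.867. A single wrong label cannot be told apart from a true control, since control 3 lay at 1.16, past the knockdowns at 0.867 to 1.02, with a gap of 0.496 of the range, and LncT was not measured. Differing progress of the control embryos from maternal to zygotic transcription also stays open. Zygotic genome activation genes were 1.86 higher (log2) in control 3 than in controls 1 and 2, and maternal genes stood at -1.20. Both lay outside the 95% range of 10000 random lists (-0.65 to 0.60 and -0.57 to 0.44). Those lists were drawn gene by gene, while members of the real lists varied together (estimated correlations of 0.412 and 0.531). That range is therefore too narrow to decide the question. Cytosolic ribosomal protein genes (2.85) and nuclear oxidative phosphorylation genes (2.42) were shifted further, and controls 1 and 2 detected fewer genes. RNA quality and transcript length were not tested.

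With single transcript rows, 14 transcripts passed, among them isoforms of CRLF3, ACBD5 and GOLPH3L, picked after their values were seen, that were exchanged within a gene. The TMBIM6 transcript listed at 0 in every control also passed, and it was among the 13 rows counted below. CRLF3 had one isoform listed at 0 in every control and at 30.2, 39.8 and 34.6 FPKM in the knockdowns, another at 39.1, 31.2 and 34.7 in the controls, at 0.0010 in knockdown 1 and listed at 0 in knockdowns 2 and 3, and a gene log2 change of 0.03. Assignment of reads to one isoform or another, flipping between single libraries, may account for such rows, since 4 of the 10 splits of the 6 libraries, the real one included, gave at least the 13 rows of the real split that were at 5 FPKM or more in 3 libraries and listed at 0 in the other 3, the highest other split giving 24. That support is weak, since the splits with 21 and 24 kept controls 1 and 2 together, while the splits that parted them gave 5 to 14. The split that put knockdown 3 with controls 1 and 2 gave 6, however. Counting the real one, 3 of 10 splits gave at least 14 transcripts past the threshold, the highest other giving 31. The real split did not stand out in this count, and 10 splits are too few for a share under 0.05.

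Pseudogenes leaned higher without control 3, with 65.9% of the 747 above 0 against 47.6% of protein-coding genes. The tables argue against expression level as the whole cause, since protein-coding genes matched on mean FPKM had 47.8% above 0, a difference of 18 percentage points. The same comparison was first made on the genes that passed without control 3 (280 pseudogenes), where the difference was 19.5 points, and was then widened to all tested genes, since genes picked for the pattern cannot test it. Reads shared with parent genes, ribosomal protein genes among them, stay open, and no biological explanation was tested.

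For genes past the adjusted threshold, other splits of the 6 libraries say nothing about chance, because a real count of 0 is reached by all 10 splits whatever the data, and the highest other gave 3. At an unadjusted p under 0.05, 4 splits, the real one included, gave at least the real 436, and the highest other gave 2463, which points to a structure of the samples, as controls 1 and 2 stood together in that split. For gene lists, 4 splits with the real one gave at least 7, with 7 as the highest other. In neither of these counts did the real split stand out from the others, and 10 splits are too few for a share under 0.05 in any case.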
